A study of Homo sapiens with 7 samples.

How the data were processed

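RNA-seq was done on HEK293 cells, an established human embryonic kidney line, carrying FLAG-HA tagged CNBP. The labels describe 3 control knockdown samples and 4 CNBP knockdown samples. Total RNA was made into directional libraries, per the labels' protocols. The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the hg19 build; their versions, settings and gene annotation are not given in the sources used here.

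One table was analysed. The authors deposited a Cuffdiff table with 63655 genes and a single FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for each of 2 conditions, headed OE and siRNA in the file. The authors also deposited a p-value and a q-value per gene, from their 1 comparison of those conditions. No heading is the same as a sample label. The siRNA condition was read as CNBP knockdown from its name and the series design alone. The labels do not explain OE, and neither they nor the table state which of the 7 samples entered each condition. If OE stands for cells that overexpress CNBP, each fold combines overexpression with knockdown. The file's own headings are therefore used throughout, and every fold is siRNA over OE.

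The table holds no value per sample, so no SD, n, left-out replicate, split of samples or test across samples could be computed, and the sequencing depth of each sample is unknown. The spread between replicates enters only through the authors' q-values. The labels do not say whether the samples came from separate cultures, so those q-values may measure technical spread. The table's status column marked 24822 genes as tested, 38171 as not tested, 613 as having too little data and 49 as having too much. Genes with too much data were listed at 0 in 1 or both conditions even where every cell uses them (RPS29, MT-RNR1), so a 0 is given only as listed.

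A gene was called where its status was tested and its q-value in the authors' deposited table was under 0.05. Folds were recomputed from the FPKM values; on the log2(FPKM + 1) scale they understate the change of low genes. The table's own log2 fold column was not used, because spreadsheet conversion had damaged some of its cells. The same conversion had turned 31 symbols into dates, which were restored through the Ensembl gene ID. Locus starts count from 0 and were printed after adding 1, which matched all 28 mitochondrial genes that have a locus of their own. A locus can be a bundle of overlapping genes and so be wider than the gene. Coordinates are hg19.

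GENCODE 29, an annotation of a later build, was used only for gene types and for the base content of 1 transcript per gene, joined by gene ID. It held 52464 of the IDs, and 93.6% of those tested. The base content is that of the longest annotated coding transcript, not of the isoforms present in these cells.

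Before the data were examined, 35 gene lists, the threshold, the alternatives and the rule for named genes were fixed. For each list, the median log2(FPKM + 1) change was placed among 10000 random lists of the same size, drawn from tested genes with a mean FPKM of at least 1 and matched in 20 bins of mean expression. Matching on GC content as well used 10 bins of mean expression and 10 of GC content, among genes with a GC value. A percentile above 97.5 or below 2.5 is described as outside the random range. These percentiles describe the 2 conditions and are not p-values, and genes of a list vary together, which random lists do not copy. On simulated changes over 20379 genes with lists of 20 genes, 5% of unshifted lists, 42% of lists shifted by 0.2 and 98% of lists shifted by 0.5 fell outside. With a simulated GC trend and no other effect, 41% of low-GC lists fell outside when matched on expression, and 5% when matched on GC as well.

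The named genes are CNBP; the 10 largest changes in each direction among called genes with 1 symbol, a locus over 300 bp and a mean FPKM of at least 1; up to 2 called genes per direction from each list, or the 2 with the highest mean FPKM where none was called; and 8 genes fixed by name, among them MYC, CCND1, ZCCHC13, LIN28B, DHX36, HNRNPK and ATF4; the remaining one is not reported here. Any other gene is said to be chosen after its values were seen.

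Alternatives changed the q-value threshold, the fold and FPKM filters, the multiple-testing adjustment, the pseudocount, the matching of random lists and the scaling. Intervals on correlations and on median ratios across genes are 95% bootstrap intervals from 1000 resamples of genes, which are not independent replicates. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.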

Results

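The data are gene expression values from HEK293 cells carrying tagged CNBP, a zinc finger protein that binds G-rich nucleic acid. The study asked what lowering CNBP does to the cells' transcripts. The labels give 3 control knockdown and 4 CNBP knockdown samples, and the table gives 1 pooled FPKM for each of 2 conditions headed OE and siRNA. The labels do not explain the heading OE, and siRNA was read as CNBP knockdown from its name and the series design alone. If OE cells overexpressed CNBP, the folds combine both changes. No value has an SD or n, because no value per sample was given, and depth per sample is unknown.

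CNBP itself (ENSG00000169714, chromosome 3, 128888327 to 128902765, hg19) was listed at 579.8 FPKM in the OE condition and 45.5 FPKM in the siRNA condition. This is a 12.7-fold lower value, or -3.67 on the log2 scale, with q = 0.00791 in the authors' deposited table, the smallest q-value it holds. ZCCHC13, a related CCHC zinc finger gene, was listed at 0 in both conditions and was not tested.

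Between the conditions 336 of 24822 tested genes were called, 142 higher and 194 lower in siRNA. With a mean of at least 10 FPKM the balance turned, to 78 higher and 71 lower. Protein-coding genes made up 105 of the higher and 139 of the lower calls, and long intergenic noncoding RNAs 10 and 22. The changes were moderate. Among coding genes with a mean of at least 10 FPKM, 123 were called, with a median of 1.82-fold and none under 1.53-fold. Only 35 of the 69 such genes that stood at least 2-fold apart were called. Before adjustment, 2712 tested genes had a p-value under 0.05 in the authors' deposited table, 1120 higher and 1592 lower.

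**Figure D1:**
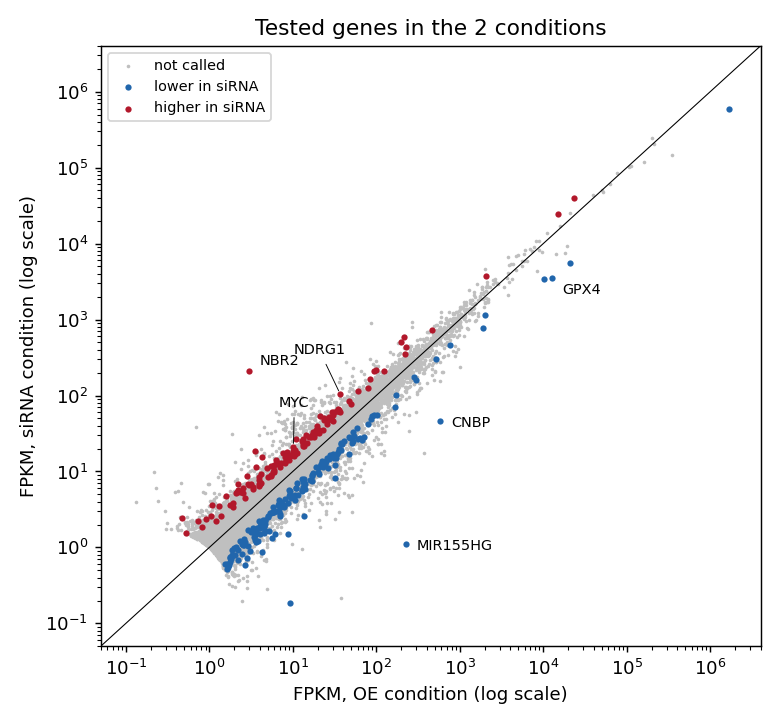
Each point is a tested gene with a mean of at least 1 FPKM, placed by its FPKM in the OE condition (x) and the siRNA condition (y), both on log axes, with the line of equal values; red and blue points were called higher and lower in siRNA. CNBP lies at 579.8 and 45.5 FPKM, and 210 genes listed at 0 in 1 condition are not drawn.

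Apart from CNBP, the largest lower calls began with MIR155HG (chromosome 21, 26934221 to 26947480), the host transcript of a microRNA, at 224 FPKM in OE and 1.11 FPKM in siRNA. How reads were assigned at this locus could not be checked without the reads, so the size of that fold is uncertain. RAB6C-AS1 stood at 9.35 and 0.188 FPKM, and the pseudogene RP11-548K12.9 at 3.10 FPKM and listed at 0. SCNN1D, an epithelial sodium channel subunit, was 5.18-fold lower, and the pseudogene CTB-134H23.3 was 5.70-fold lower. GPX4 (chromosome 19, 1103936 to 1106787), the glutathione peroxidase that reduces lipid peroxides, fell from 12657 to 3539 FPKM, 3.58-fold. Both values stood far above those of GAPDH, at 941 and 1050 FPKM, a gene chosen after its values were seen. Read assignment at the GPX4 locus could not be checked either, so the size of this fold is uncertain too. ZNF76 was 3.87-fold lower, COX6B2, a testis form of a cytochrome c oxidase subunit, 4.30-fold lower, and SNORD3A, the U3 small nucleolar RNA, 3.01-fold lower. SNORD3A has near-identical copies, and pseudogenes share sequence with their parents, so reads could be divided among them. All of the called genes named here had q = 0.00791 in the authors' deposited table.

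The largest higher call was NBR2 (chromosome 17, 41277627 to 41305688), a noncoding gene that shares a promoter region with BRCA1, at 2.99 FPKM in OE and 212 FPKM in siRNA, a fold with the same uncertainty. The noncoding C1orf132 was 5.34-fold higher, MIR503HG 3.69-fold and RP11-274B21.10 5.13-fold. NDRG1 (chromosome 8, 134249414 to 134314265), a stress-responsive gene, rose from 37.0 to 104 FPKM. The chemokine receptor CXCR4 was 3.10-fold higher, the desmosomal cadherin DSC2 3.16-fold, SKIDA1 3.08-fold and ZNF711 2.56-fold. GNPNAT1, an enzyme of UDP-GlcNAc synthesis, went from 21.2 to 52.98 FPKM with q = 0.0177 in the authors' deposited table, the others having q = 0.00791. Strand handling in the counting is not stated, so overlapping and antisense genes are uncertain.

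Lists on translation, the process named by the series, held calls in both directions. Of 78 tested cytoplasmic ribosomal protein genes, 2 fell and none rose. RPL18 went from 1899 to 785 FPKM and RPL5 from 769.6 to 458 FPKM. The list median was 0.12, at percentile 78.6 of random lists. None of 16 other TOP mRNAs, which share a 5' pyrimidine tract, was called (percentile 45.8); GNB2L1 was at 3746 and 4087 FPKM and EEF2 at 3430 and 2685 FPKM. Among 37 genes of the initiation factor list 1 rose and 2 fell (percentile 67.8). The count of 2 lower stood at percentile 98.1 of counts in random lists, whose mean was 0.29. This does not single the list out. Counts of genes called higher lay at 99.7 for mitochondrially encoded mRNA genes, 99.6 for immediate early genes and 99.0 for glycolysis and hypoxia genes. Such counts were taken for 33 lists in both directions, so some may lie this high by chance. EIF1AX was 2.18-fold higher, EIF3K 1.89-fold lower, and EIF4EBP2, which binds eIF4E and is not itself an initiation factor, 1.87-fold lower. None of 20 cytosolic aminoacyl-tRNA synthetases was called (percentile 17.9); MARS was at 389.8 and 397 FPKM and IARS at 234 and 276 FPKM. None of 36 nucleolar ribosome biogenesis genes was called (percentile 95.5), with FBL at 697 and 513 FPKM and NCL at 373 and 445 FPKM. Matched on GC content as well, that list lay at percentile 99.8.

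Among 33 genes of the ATF4 and integrated stress response list 1 fell, CBS, an enzyme of transsulfuration, by 1.76-fold. Of the 32 with a mean of at least 1 FPKM, 11 had a higher value in siRNA. The list median of -0.16 lay below the random range, at percentile 0.82, and ATF4 itself was at 178 and 161 FPKM without a call. Without matching on expression the percentile was 4.24. Of 13 cytosolic heat shock genes 1 rose. It was HSPA1B, from 80.2 to 127 FPKM, which shares nearly all of its sequence with HSPA1A, so that reads could be divided between them. The median of 0.35 lay above the random range, at percentile 98.1. None of 24 endoplasmic reticulum chaperone and unfolded protein genes was called (percentile 86.5); CANX was at 466 and 543 FPKM and P4HB at 345 and 389.0 FPKM.

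RNA-binding groups were next. Of 18 G-quadruplex-binding proteins and helicases 1 rose, DDX3X, an RNA helicase, from 84.2 to 167 FPKM. The list median was 0.35, above the random range at percentile 99.7. DHX36, a G-quadruplex helicase, was at 70.5 and 103 FPKM and HNRNPK at 222 and 229 FPKM, neither called. Of 39 splicing factors 1 rose, SRSF6, by 1.79-fold (percentile 77.2). None of 17 tested genes of the fixed CCHC zinc knuckle list was called (percentile 70.5), with ZCCHC11 at 99.2 and 108 FPKM and SRSF7 at 89.5 and 117 FPKM. ZCCHC12, outside that list and chosen after its values were seen, was called 2.95-fold higher, from 1.60 to 4.71 FPKM. None of 13 genes of the small RNA silencing machinery was called (percentile 96.8); DROSHA was at 183 and 165 FPKM and XPO5 at 166 and 147 FPKM. LIN28B, at 15.8 and 22.96 FPKM, was not called. None of 26 nonsense-mediated decay substrates and snoRNA hosts was called (percentile 11.5), with SNHG3 at 7833 and 9146 FPKM and SNHG7 at 6410 and 5828 FPKM. Whether reads of the hosted snoRNAs were counted at these loci could not be checked, so the level of the host transcripts is uncertain.

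In growth and signalling, MYC (chromosome 8, 128747680 to 128753674) was 2.06-fold higher, from 10.2 to 20.97 FPKM, with q = 0.00791 in the authors' deposited table. CCND1, at 50.1 and 74.9 FPKM, was not called. MYC and IER3, which was 2.36-fold higher, were the 2 of 27 immediate early genes that rose (percentile 78.2), and MYC was the 1 of 18 WNT targets (percentile 89.9). Matched on GC content as well, these lists lay at percentiles 98.3 and 97.7. Of 14 NF-kB targets 1 rose, the chemokine gene IL8, from 0.738 to 2.26 FPKM. This list lay at percentile 97.54, just above the range, and at 92.6 with a mean of at least 5 FPKM. Of 24 interferon-stimulated genes 1 fell, ISG15, by 1.79-fold (percentile 20.2). None of 13 TGF-beta and BMP targets was called (percentile 65.6); TGFB1 was at 47.6 and 49.7 FPKM and SKIL at 22.4 and 40.3 FPKM.

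No gene of the 3 fixed cell cycle and histone lists was called. The 35 genes of G2/M and mitosis had a median of -0.10, below the random range at percentile 0.84. PRC1 was at 424 and 426 FPKM and CDK1 at 226 and 245 FPKM. Without matching on expression the list lay at percentile 13.1, and matched on GC content as well at 0.03. The 40 genes of G1/S and DNA replication lay at percentile 14.99, with MCM4 at 561 and 761 FPKM and MCM7 at 357 and 347 FPKM. Of 18 replication-dependent histone genes, HIST1H3B was at 2149 and 1786 FPKM and HIST1H1C at 1294 and 1233 FPKM (percentile 4.59). None of 22 p53 targets was called (percentile 36.2); CCNG1 was at 364 and 397 FPKM and MDM2 at 199 and 299.7 FPKM. Of 28 apoptosis regulators 1 rose, CYCS, which encodes cytochrome c, by 1.89-fold (percentile 56.7).

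All 13 tested mitochondrially encoded mRNA genes had a higher value in siRNA, by 1.103- to 1.61-fold, and 2 were called. MT-ND2 rose from 219 to 353 FPKM and MT-ND3 from 459.6 to 737 FPKM. The median of 0.48 lay above the random range, at percentile 99.9, and at 99.6 when matched on GC content as well. None of 53 nuclear-encoded oxidative phosphorylation genes was called (percentile 35.3), with COX6B1 at 976 and 974.9 FPKM and ATP5B at 897 and 846 FPKM. Of 27 glycolysis and hypoxia genes 2 rose, NDRG1 and BNIP3, a mitophagy receptor that went from 14.7 to 23.7 FPKM; the list lay at percentile 85.0, and at 98.5 matched on GC content as well. Of 27 cholesterol genes 1 rose, the fatty acid desaturase SCD, by 1.76-fold (percentile 40.2). No gene was called among 31 proteasome subunits (percentile 83.7; PSMD8 at 224 and 259 FPKM, PSMB4 at 173 and 163 FPKM) or 27 autophagy and lysosome genes (percentile 16.3; GLA at 98.5 and 284 FPKM, CTSB at 109 and 106 FPKM).

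Lists of neuronal, matrix and other cell type genes held few calls. Of 15 tested neuronal genes 1 rose, the neurofilament gene NEFL, by 1.80-fold (percentile 9.81). None of 30 matrix and adhesion genes was called (percentile 81.9; TIMP1 at 88.4 and 91.9 FPKM, VCAN at 71.2 and 84.8 FPKM). None of 7 fibroblast and smooth muscle markers (percentile 3.62; ACTA2 at 21.1 and 12.5 FPKM, COL1A1 at 6.60 and 4.79 FPKM) or 5 keratin-rich epithelial markers (percentile 91.3; EPCAM at 35.3 and 52.4 FPKM, KRT19 at 17.6 and 18.4 FPKM) was called. The keratin list lay at percentile 98.2 when matched on GC content as well. Its percentiles of 91.3 and 98.2 rest on only 4 genes with a mean of at least 1 FPKM. Matched on expression without that filter, the list lay at 65.1. Blood markers and hepatocyte markers had 2 tested genes each, too few for a percentile, with FCER1G at 2.76 and 1.70 FPKM, CD14 at 0.731 and 0.489 FPKM, TF at 1.91 and 0.766 FPKM and HP at 0.900 and 1.07 FPKM.

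**Figure D2:**
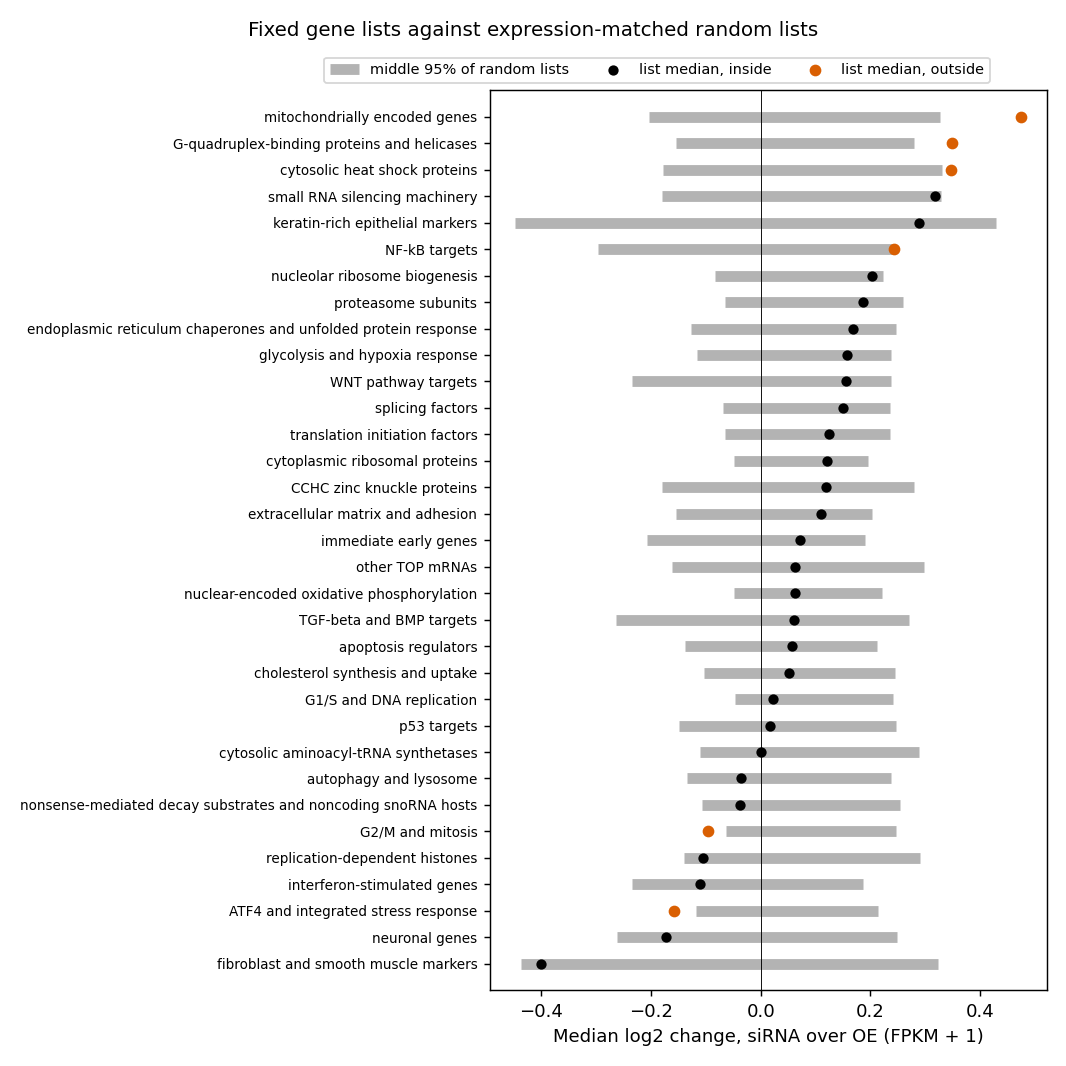
Points are the median log2(FPKM + 1) change, siRNA over OE, of each fixed list with enough expressed genes, and grey bars span the middle 95% of 10000 random lists matched on expression. Of 33 lists, 4 lay above their bar and 2 below it (orange).

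Taking the lists as a whole, 14 of their 834 tested genes rose and 6 fell. With 33 lists, 1.65 would lie outside the random range by chance if lists behaved as random genes, against the 6 seen.

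Changes went with the base content of the transcripts. Coding genes called higher had a median GC content of 41.7%, those called lower 58.0% and all 12972 expressed coding genes 48.6%. In the decile of genes with the lowest GC content the median change was 0.28, with 28 genes called higher and 0 lower. In the decile with the highest it was -0.22, with 0 called higher and 37 lower. Across these genes Spearman's rho was -0.443 (95% interval -0.458 to -0.430). Chromosome 19, which is GC-rich, held 7.85% of tested coding genes, and 25 of the 139 lower but 2 of the 105 higher calls.

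**Figure D3:**
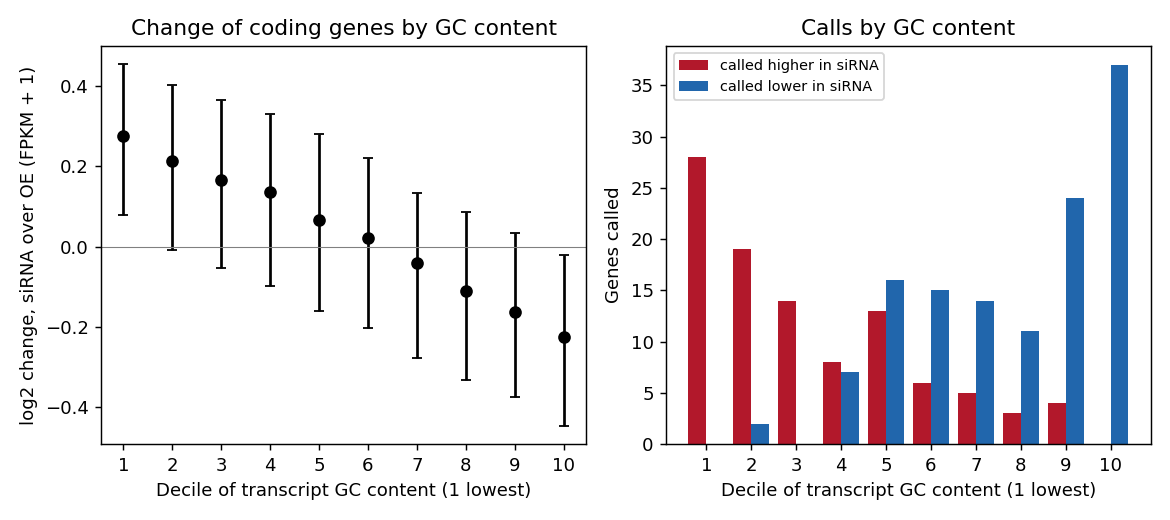
Left, the median (points) and middle 50% (bars) of the log2(FPKM + 1) change of coding genes in deciles of transcript GC content; right, the number of genes called higher (red) and lower (blue) in each decile. The median falls from 0.28 in the lowest decile to -0.22 in the highest.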

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

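CNBP stayed between -3.64 and -3.76 on the log2 scale under every alternative run on it. Alternatives restricted to coding genes, without genes listed at 0, or using GC content were chosen after seeing the data; the others were fixed before the data were examined. The counts of calls moved with the threshold by construction: at a q-value under 0.01 there were 70 higher and 87 lower, at 0.1 there were 240 and 335, and at a mean of at least 10 FPKM, where fewer genes enter, 78 and 71, so that higher calls outnumbered lower ones. The other alternatives gave 105 to 142 higher and 139 to 194 lower. Recomputing the Benjamini-Hochberg adjustment over tested genes returned the same 142 and 194 calls. The median ratio of the conditions was 1.00, so scaling by it moved almost nothing and is no test of these counts. Among list genes, 6 were called lower and 3 at a q-value under 0.01.

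Of 33 lists, 4 lay above the random range. Without matching on expression 7 did, 3 of them among those 4. Matched on GC content as well 9 did, all 4 included. That matching also used 10 expression bins in place of 20 and only genes with a GC value. For the histone list that matching is void, because 72.2% of its genes had a GC value. Below it lay 2 lists, and without matching 1 list, which was neither of them; the cause was not tested. The remaining alternatives kept both lower lists and at least 3 of the higher ones. No list outside its range changed side. No paired analysis was possible because the table has no value per sample, and for the same reason leaving out a replicate was not run. Agreement of knockdown conditions was not run, because the table holds 1 comparison. Depth per sample is unknown, so how far it limits the calls cannot be given.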

Other observations

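Everything in this paragraph was chosen after the values were seen. Of 11 tested U5 small nuclear RNA genes, 4 were called higher: RNU5A-1 (23153 to 39410 FPKM), RNU5B-1, RNU5F-1 and RNU5E-4P; these copies are alike enough to share reads. RNU4-2 was at 210259 and 203914 FPKM and RMRP at 39622 and 44279 FPKM, neither called. MIR3687, a short gene annotated as a microRNA, made up 37.6% of the summed FPKM in OE and 18.4% in siRNA. It was called 2.85-fold lower, and MIR3648, on the same chromosome, 3.69-fold lower. Which RNA their reads came from could not be checked, so these values are not read as microRNA levels. TSC22D3, a glucocorticoid-induced gene, was 1.92-fold higher and CAPZA2, an actin capping subunit, 2.17-fold higher. The genes beside the largest calls did not follow them: BRCA1 was at 42.3 and 25.6 FPKM and NBR1 at 18.01 and 13.6 FPKM beside NBR2, and MRPL39 at 57.7 and 65.0 FPKM beside MIR155HG, none called.

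Of 6 families also chosen afterwards, 254 small nucleolar RNAs (median 0.24) lay above all 10000 random lists. The 1148 long intergenic noncoding RNAs (median -0.17) lay below all of them. Both held with or without matching on GC content. Yet none of those small nucleolar RNAs was called higher and 1 was called lower, against means of 2.34 and 2.49 in random lists. The 427 ZNF genes lay at percentile 99.8, and at 52.4 when matched on GC content. Mitochondrial ribosomal proteins, solute carriers and DEAD-box helicases lay at percentiles 67.0, 16.4 and 47.2.

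Tests of G content alone, of transcript length and of mitochondrial tRNA were chosen only after the result they bear on was seen. Transcripts low in GC were higher and those high in GC lower. With length held fixed, rho with GC stayed at -0.428, and C weighed slightly more than G (difference 0.0462, 95% interval 0.0124 to 0.0819), which argue against length and against G content alone. The density of TGGAG, the core of a G-rich CNBP motif, had the most negative partial rho of the 20 arrangements of its bases (rank 1, rho -0.073), an outcome at either end that chance gives in 2 of 20 cases; with that density fixed rho with GC was still -0.377, so it does not account for the trend. Long intergenic noncoding RNAs showed the trend too (rho -0.263, interval -0.314 to -0.207), as a GC bias between the libraries would give. Such a bias may be the cause, and an effect of CNBP or of the OE condition stays open, since library and condition go together.

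How far the trend made up the calls is open. With the median change at each GC content removed, the called coding genes had a median change of 0.72 in the direction of their call, against 0.81 before. This decides nothing: the genes were picked for large changes, and the trend spans only -0.25 to 0.31, too little to halve that median. The q-values were not recomputed, so how many calls would remain is not known.

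The 13 mitochondrially encoded mRNA genes stood higher together. The list lay at percentile 99.64 of random lists matched on expression and GC content, which argues against the GC trend as the whole cause. Random lists so matched had a median change of 0.21, against 0.07 when matched on expression alone. A part played by the GC trend therefore stays open. Genes of a list also vary together, which random lists do not copy. Scaling between the conditions was not tested separately; a percentile compares the list with other genes, so a factor common to all genes does not enter it. In these pooled values an equal rise of every mitochondrial transcript is also argued against. The 22 tRNA genes had a median ratio of 0.995 (interval 0.779 to 1.15), 11 of 22 had a higher value and 0 were called. The 13 mRNA genes had a median ratio of 1.39 (interval 1.31 to 1.47). Both intervals come from resampling genes, so they do not measure the spread between replicates. The rule for reading the tRNA values was set after they were seen, tRNA genes are short and their ratios ran from 0.410 to 3.40, and a smaller rise of tRNA stays open. A change in mitochondrial mRNA with CNBP is a hypothesis that replicate values would be needed to test.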
